A study of Mus musculus with 48 samples.

How the data were processed

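Bulk RNA sequencing of mouse epidermis gave 48 libraries. Per the labels, the cells were epidermal cell suspensions from the skin of mice 47 weeks old, labelled ColXIV KO or ColXIV WT, taken at Zeitgeber times (ZT) 0, 4, 8, 12, 16 and 20, and the libraries were stranded mRNA libraries. The 12 groups of genotype and time held 4 biological replicates each. The authors deposited raw counts per gene, keyed by Entrez gene ID, with no normalisation. The values were whole numbers that summed to between 35.6 and 43.7 M per library. Per the submitters' processing notes, Trim Galore, STAR 2.7.10a, featureCounts and the GRCm38 (mm10) assembly were used. Their roles and order, the gene annotation and the strand setting are not given in the sources used here.

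The table held 27179 gene IDs, of which 3698 had no read in any library. Symbols and GRCm38 positions were matched by ID, for 25275 IDs through a RefSeq gene table and for 18 through GENCODE. The other 1886 IDs, with 4.65% of all counts, stayed unnamed. Library totals were scaled by TMM in edgeR 4.0.16 (normalisation factors 0.919 to 1.07), and levels are TMM-scaled counts per library in CPM. Genes were kept by filterByExpr with the 12 groups, which left 17068 genes, 16082 of them named. The spread between replicates covers animals, preparation and counting together.

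All 48 libraries shared 1 estimate of each gene's spread. The model held 12 group means and was fitted with glmQLFit (robust), and each contrast was tested with glmQLFTest in edgeR, with p adjusted by Benjamini-Hochberg and called under 0.05. Contrasts were KO minus WT averaged over the 6 times, KO minus WT at each time, and an F test that the 6 differences are equal. A second model held genotype and, within each genotype, a cosine and a sine with a period of 24 h. From it came the genes rhythmic in each genotype, over both genotypes, and with a different rhythm, the last tested as a difference of the terms. Amplitude is the log2 distance from the mean to the peak, and the fold from trough to peak is 2 raised to 2 amplitudes. Standard errors of amplitude and peak time are jackknife errors over libraries within groups. All log2 fold changes are the libraries labelled KO over those labelled WT, with their standard errors.

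Gene lists were fixed before the data were examined, as were the models, the threshold, the rule for named genes and 17 of the alternatives. The pathway lists were core clock, YAP/TAZ targets, epidermal inflammation, interferon response, immediate early and AP-1, MHC class I presentation, basal keratinocyte, spinous and granular differentiation, stress and wound keratinocyte, cell cycle S phase, cell cycle G2 and M phase, nuclear-encoded oxidative phosphorylation, glycolysis, NRF2 and oxidative stress, senescence and p53, lipid and barrier synthesis, basement membrane and integrin adhesion, and heat shock. The cell type lists were hair follicle stem and outer root sheath, anagen hair shaft and inner root sheath, sebaceous gland, fibroblast and dermis, Langerhans and dendritic cell, T cell, macrophage and monocyte, neutrophil, mast cell, melanocyte, endothelial, skeletal muscle, adipocyte, erythrocyte, Schwann cell, and mitochondrially encoded genes. These 34 lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Each list's test was repeated with an estimated correlation and with fry. Neighbours of Col14a1 on chromosome 15 and sex-linked check genes (Xist, Tsix, Ddx3y, Eif2s3y, Kdm5d, Uty) served as technical lists.

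Genes were named by a fixed rule. Col14a1 was always named. For the averaged effect, called genes with a mean of at least 1 CPM and the same sign at all 6 times were ranked, predicted genes and sex-linked check genes aside, and the 12 largest positive and 12 largest negative fold changes were named. From each list up to 4 called members were named, or, where none was called, up to 2 members with the highest mean CPM, as values. At each time the 3 largest positive and the 3 largest negative fold changes among called genes of at least 1 CPM were named. For the interaction and the difference in rhythm it took the 10 smallest p among called genes. For rhythm it took every measured core clock gene and, among other called genes of at least 1 CPM, the 8 largest amplitudes per genotype. Where fewer than 5 genes were called, the 5 smallest p were named and said not to pass. Other genes are named as examples of lists or because few were called, and were chosen after their values were seen.

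Alternatives fixed beforehand replaced 1 choice at a time. They were RLE size factors, DESeq2 1.42.0, limma-voom, no filter beyond 1 read, a filter of 1 CPM in at least 24 libraries, the replicate number as a block, 2 surrogate variables (svaseq, sva 3.50.0), covariates for fibroblast and anagen hair make-up, terms for sex-linked expression (log2 CPM of Xist and of the summed Y-linked genes), each library left out in turn, only the 8 libraries of a time, a 5-df test over the 6 times, glmTreat against a fold of 1.2, camera with an estimated correlation, fry, a prior count of 0.5, and Col14a1 scaled by library totals alone. Another 8, which concern sex-linked expression, chromosome 15 and 3 libraries labelled WT, were chosen after seeing the data. Some of these joined the terms for sex-linked expression with another change, the 5-df test or camera with an estimated correlation. Genotype was shuffled within time and time within genotype, with 100 splits each, the real one included. All 35 splits of the 8 libraries of a time were run. Each was applied to the 6 times at once, with the spread estimated again from all 48 libraries. Permutation tests of single measures used 100000 draws. Transcripts of called genes were compared with BLAST 2.17.0. Analyses ran in R 4.3.3 and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

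The models were tested on simulated data with the real library sizes and each gene's estimated spread, 16957 genes and 50 changed genes at each fold. Changed genes had a mean of at least 1 CPM. Genes were drawn independently, without the sex-linked differences or the correlation between genes of the real libraries, so the shares below hold for such data only. The averaged contrast recovered 80% of genes changed 1.25-fold, 96% at 1.5-fold and 100% at 2-fold. A change at 1 time was recovered for 38%, 70% and 92% of genes at these folds by the test of that time, and for 12%, 52% and 80% by the interaction test. A rhythm in KO alone was recovered as a difference for 14%, 62% and 84%. Simulated rhythms were exact cosines, so these shares do not cover rhythms of other shapes. Between 1.4% and 6.13% of calls in these simulated data were false. Replicate numbers were checked for pairing: 11 of 24 same-numbered pairs of libraries had deviations correlated above 0.1, with a range of -0.365 to 0.636. Across groups the mean correlation was 0.0215 for the same number and -0.00738 for other numbers, and 20 of 48 libraries were closest to their own number. Some relation by number therefore stays possible, and the block was run only as an alternative. In 72 pairs of libraries of 1 group, counts differed by 8.51 to 96.7 in chi-square per degree of freedom, so none was a copy of another. No library was left out of the comparisons, and 0 sample columns went unused.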

Results

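Epidermis of aged mice, 47 weeks old and labelled either knocked out for collagen type XIV (KO) or wild type (WT), was profiled by bulk RNA sequencing over 1 day. Libraries came from Zeitgeber times (ZT, hours after lights on) 0, 4, 8, 12, 16 and 20, with 4 libraries in each of the 12 groups and 48 in all. The series title names the clock factor BMAL1, the Hippo pathway effector YAP, enhancers and inflammation. Total counts per library ranged from 35.6 to 43.7 M, with a median of 40.8 M in libraries labelled WT and 40.6 M in libraries labelled KO. After the low-count filter 17068 genes were tested.

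Sex-linked genes divided the libraries into 2 clear types. Xist, the RNA that coats the inactive X chromosome, was at 1350 CPM or more in 24 libraries and at 4.36 CPM or less in the other 24. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together were at 183 CPM or more in the latter and at 0.361 CPM or less in the former. Tsix, the antisense transcript of Xist, averaged 64.7 CPM in libraries labelled WT and 35.0 CPM in those labelled KO. Of the libraries labelled WT 15 of 24 expressed Xist, and of those labelled KO 9 of 24 did (2-sided Fisher's exact test, p = 0.148). Sex-linked type accounted for 92.4% of the variance of the first principal component, time for 12.8% and genotype for 4.28%, and that component held 25% of all variance. Values from a fit with terms for sex-linked expression are therefore given where they change the call of a named gene or a list in the averaged effect.

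Col14a1, which encodes the collagen XIV chain that the labels give as knocked out, was measured first to check the labels. Its counts were higher, not lower, in the libraries labelled KO. In these it averaged 61.3 CPM ± 8.41 (SD, n = 24), from 45.3 to 80.1 CPM or 1777 to 3309 counts. In libraries labelled WT it averaged 1.23 CPM ± 0.939 (SD, n = 24), from 0.261 to 4.13 CPM or 10 to 171 counts. The gene (Entrez 12818) lies on chromosome 15 at 55307644 to 55520803 (GRCm38). Its log2 fold change, libraries labelled KO over those labelled WT, was 5.69 ± 0.19 (SE) with an adjusted p of 2.4e-23 in edgeR, and it was positive at 6 of 6 times. Single times gave 5.12 at ZT0, 6.10 at ZT4, 5.73 at ZT8, 6.16 at ZT12, 5.17 at ZT16 and 5.84 at ZT20, with SE of 0.44 to 0.49. The direction is therefore opposite to what a loss of the transcript would give under the labels, and every comparison that follows is written by label, as libraries labelled KO against libraries labelled WT.

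**Figure D1:**
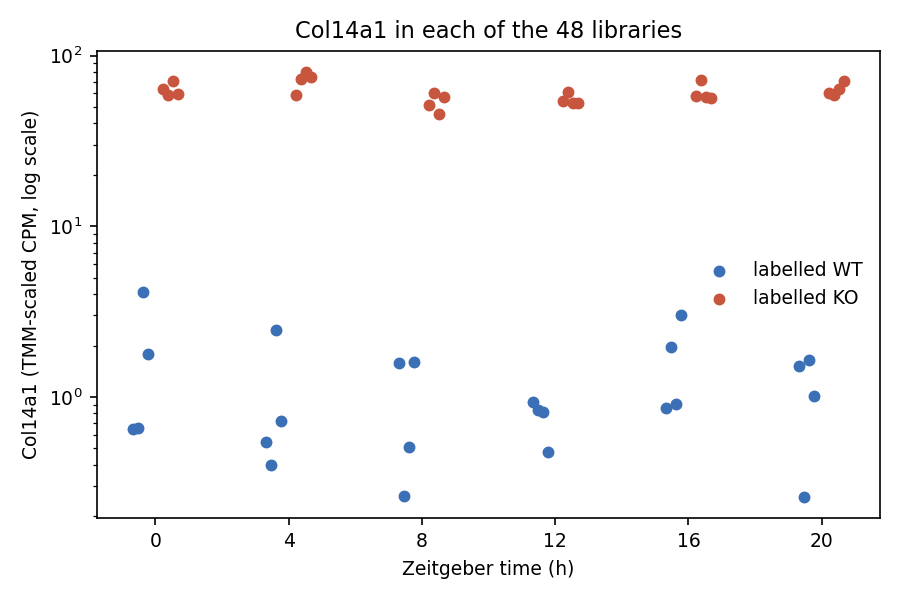
Col14a1 level in CPM (log axis) against Zeitgeber time in hours, 1 point per library, 4 per group, with colours for the label. The 24 libraries labelled KO lie between 45.3 and 80.1 CPM, all above the 24 labelled WT, which lie between 0.261 and 4.13 CPM.

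Col14a1 level varied little among libraries labelled KO although their dermal content varied. The SD of its log2 CPM was 0.195 in these and 1.05 in libraries labelled WT, while the SD of the fibroblast and dermis list mean was 0.726 and 0.731. Col1a1, a main chain of dermal collagen I, ranged from 0.441 to 46.4 CPM in libraries labelled KO and from 0.288 to 95.1 CPM in those labelled WT. Col14a1 and the list mean were related in libraries labelled KO, with r = 0.573 (permutation p = 0.00344) and rho = 0.543 (permutation p = 0.00676, Benjamini-Hochberg adjusted 0.0135 over the 2 relations computed). Without the 2 libraries farthest from the median of the list mean, r was 0.56 and rho 0.506. In libraries labelled WT r was 0.401 (permutation p = 0.0519) and rho 0.437 (permutation p = 0.0334, adjusted 0.0334), but r fell to 0.15 and rho to 0.285 without the 2 farthest libraries, so that relation rested on those libraries.

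The main comparison asks what differs between the genotypes over the day. Stk3, which encodes the Hippo kinase MST2 that restrains YAP, was higher in libraries labelled KO (17.6 against 11.6 CPM, log2 fold change 0.60 ± 0.05, adjusted p = 2.0e-11). Has2, a hyaluronan synthase, was lower (0.973 against 1.95 CPM, -1.0 ± 0.15, adjusted p = 2.6e-05), as was Matn2, a matrilin of the extracellular matrix (16.4 against 25.3 CPM, -0.65 ± 0.08, adjusted p = 1.5e-07). Counts of Rpl30, a ribosomal protein gene, were lower (260 against 373 CPM, -0.53 ± 0.06, adjusted p = 1.0e-08), as were those of Polr2k, a subunit of the RNA polymerases (5.47 against 9.14 CPM, -0.73 ± 0.06, adjusted p = 1.7e-11). The transcript of the pseudogene Gm5481, which was higher, matches that of Rpl30 at 95.65% over 345 bases. Reads of Rpl30 assigned to a copy and a change of the gene itself cannot be told apart from counts per gene. These 5 genes all lie on chromosome 15, and each had the same sign at 6 of 6 times, as the naming rule required.

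Other named genes that were higher in libraries labelled KO included Tspyl5 (1.69 ± 0.15), Pnpla3, a lipase of lipid droplets (0.85 ± 0.16), Angpt1, a ligand of the Tie2 receptor (0.76 ± 0.16), and Col6a6, a collagen VI chain (0.75 ± 0.13). Them6 (0.70 ± 0.12), Jrk (0.61 ± 0.08), Mtss1, which binds actin and membranes (0.37 ± 0.04), and Emc2 of the ER membrane complex (0.24 ± 0.04) were also higher. Their adjusted p ranged from 1.7e-10 for Tspyl5 to 0.0092 for Angpt1, and all but Col6a6 lie on chromosome 15. Pnpla3 was at 79.8 CPM in libraries labelled KO and 44.7 CPM in those labelled WT. Among interferon-induced genes, Oasl2 (0.65 ± 0.14, adjusted p = 0.0113) and the GTPase gene Tgtp2 (0.87 ± 0.20, adjusted p = 0.0288) were higher. Genes lower in libraries labelled KO included the snoRNA host gene Snhg18 (-1.08 ± 0.10), Laptm4b of lysosomal membranes (-0.56 ± 0.07), the transcytosis gene Mal2 (-0.46 ± 0.06), Atpsckmt, a lysine methyltransferase gene (-0.39 ± 0.04), and Nudcd1 (-0.31 ± 0.05), with adjusted p from 3.9e-10 for Snhg18 to 2.5e-05 for Nudcd1. The acyl-CoA synthetase gene Acsm1 (-0.44 ± 0.10, adjusted p = 0.0394), Ly6g6g (-0.40 ± 0.10, adjusted p = 0.0473) and Tomm6os (-0.24 ± 0.05, adjusted p = 0.0111) were lower too. Of these lower genes all but Acsm1 and Tomm6os lie on chromosome 15. The same sign at 6 of 6 times was a condition for naming these genes, so it is no evidence of their consistency. The alarmin gene S100a8, from the inflammation list, was low throughout and fell from 0.593 to 0.183 CPM (-1.52 ± 0.29, adjusted p = 0.0030). With terms for sex-linked expression, the calls of Acsm1 and Tgtp2 ended (both adjusted p = 0.0587), with the replicate block those of Ly6g6g (0.0716) and Tgtp2 (0.0627), and in limma-voom those of Ly6g6g (0.0523), Tgtp2 (0.199) and Oasl2 (0.104). Adjustment over the genes not placed on chromosome 15 alone ended those of Acsm1 (0.108) and Tgtp2 (0.0884). The stricter filter ended that of Ly6g6g (0.0508) and surrogate variables that of Tgtp2 (0.0601). All 4 ended without the 3 libraries labelled WT (ZT4 replicates 3 and 4, ZT16 replicate 2) in which the pseudogene Gm5481 was at a level like that under the KO label (adjusted p = 0.136 for Acsm1, 0.165 for Ly6g6g, 0.1205 for Tgtp2 and 0.0555 for Oasl2). Transcripts of Tgtp2, Tomm6os, Col6a6 and Oasl2 matched those of other genes, Tgtp1 at 99.75% over 2811 bases, Prickle4 at 100% over 323, Col6a5 at 96.85% over 572 and Cdca8 at 90.09% over 111. Leaving out 1 library ended the call of Acsm1 in 33 of 48 cases (adjusted p up to 0.0835, without WT ZT0 replicate 4), of Ly6g6g in 36 (up to 0.1004, without WT ZT12 replicate 1) and of Tgtp2 in 13 (up to 0.0629, without KO ZT0 replicate 1).

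In all, 58 of 17068 genes were called in edgeR, 33 higher and 25 lower in libraries labelled KO. At an unadjusted p under 0.05 there were 1177 genes. Of the 58, 53 had the same sign at 6 of 6 times, and 58 had the same sign in libraries of both sex-linked types. With terms for sex-linked expression the count was 185 (60 higher and 125 lower), of which 54 were among the 58, all with the same sign. The 24 libraries that expressed Xist alone gave 26 calls, and the other 24 gave 34. These shared 15 genes, each with the same sign in both types, where independent lists would share 0.0518. Within each type alone the calls of Has2 (adjusted p = 0.246 with Xist and 0.137 in the others), Pnpla3 (0.984 and 0.191), S100a8 (0.984 and 0.0757), Oasl2 (0.984 and 0.207), Emc2 (0.187 and 0.267), Tomm6os (0.984 and 0.267), Ly6g6g (0.984 and 0.114) and Tgtp2 (0.984 and 0.267) ended. Those of Mal2 (0.0597), Angpt1 (0.2404), Them6 (0.984) and Jrk (0.319) ended in libraries with Xist alone, and those of Matn2 (0.141), Laptm4b (0.0583), Nudcd1 (0.0676), Col6a6 (0.368) and Acsm1 (0.615) in the others.

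Called genes lay mostly on the chromosome of Col14a1. Of the 51 called genes with a known position, 37 (72.5%) were on chromosome 15, which holds 4.08% of the 16073 placed genes tested (odds ratio 65.7). There 20 were higher and 17 lower in libraries labelled KO. They included Fzd6, a Wnt receptor gene (130 against 112 CPM), and the syndecan gene Sdc2 (24.1 against 20.3 CPM). Their starts ran from 31.6 to 84.2 Mb (GRCm38), with 29 of 100 tested genes called between 30 and 60 Mb, 0 of 19 between 60 and 70 Mb and 8 of 241 between 70 and 85 Mb. In edgeR 0 of 71 genes were called below 30 Mb and 0 of 225 above 85 Mb, where 6 and 28 had an unadjusted p under 0.05 and DESeq2 called 0 and 1 and limma-voom 0 and 0 (between 60 and 70 Mb, 1 at an unadjusted p under 0.05, 0 and 0). Among the 34 measured neighbours of Col14a1 on the fixed list, 3 were called (Mtss1 higher, Mal2 and Has2 lower), and 5 adjusted over the list alone, 2 higher and 3 lower. With terms for sex-linked expression all 37 stayed called, and chromosome 15 held 30.2% of the placed calls.

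**Figure D2:**
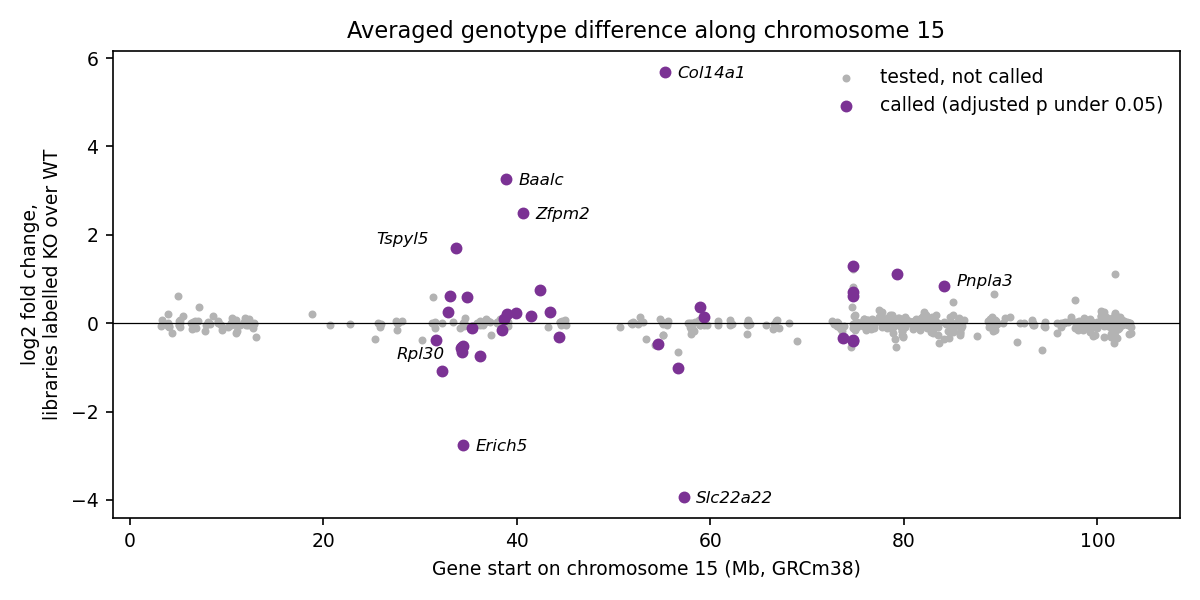
Averaged log2 fold change, libraries labelled KO over those labelled WT, against gene start on chromosome 15 in Mb (GRCm38), with 1 point per tested gene and called genes in colour. The 37 called genes start between 31.6 and 84.2 Mb and go both ways, 20 higher and 17 lower.

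Interferon response genes were the list with the clearest rise in libraries labelled KO. Of 28 measured members 27 had a positive fold change, with a median of 0.24. Examples were the GTPase gene Iigp1 (1.11 ± 0.28) and Oasl2, the 1 member called among all genes. Adjusted over the list alone 19 members passed, all higher. Camera gave an adjusted p of 3.6e-16, but the adjusted p = 0.128 with an estimated correlation, and 0.036 with fry. With genotype shuffled within time, camera with the preset correlation gave this list an adjusted p as low as 1.2e-11. Its p with that correlation therefore overstates the evidence. The list mean was 0.268 ± 0.0724 log2 higher (95% interval 0.121 to 0.415, within-time permutation p = 0.00083). Mean differences at single times ran from 0.00107 at ZT20, level between the labels and with a median of -0.0279, to 0.525 at ZT16. Within time and sex-linked type it was 0.294 (permutation p = 0.00172). These permutation p were not adjusted over the lists. MHC class I presentation genes, many of them interferon-induced, had 14 of 14 members positive and a median of 0.07 (adjusted p = 2.2e-08; adjusted p = 0.433 with an estimated correlation and 0.172 with fry), with medians of -0.042 at ZT8 and -0.050 at ZT20, and 0 were called in edgeR among all genes or adjusted over the list alone (5 at an unadjusted p under 0.05; 0 in DESeq2 and 0 in limma-voom). H2-K1 and H2-D1, the classical class I heavy chains, had values of 0.05 ± 0.03 and 0.05 ± 0.03 at 1483 and 1235 CPM.

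Lists of YAP/TAZ targets, immediate early genes, differentiation, lipid synthesis and glycolysis had small positive medians by label and were called by camera with the preset correlation. Such calls are weak evidence, since 48 of 100 shuffles of genotype within time, the real split included, called as many lists. YAP/TAZ targets had 17 of 21 members positive and a median of 0.05 (adjusted p = 0.0058; adjusted p = 0.556 with an estimated correlation), with 0 called among all genes in edgeR, DESeq2 or limma-voom, 3 at an unadjusted p under 0.05 and 1, the growth factor gene Tgfb2 (0.26 ± 0.08), adjusted over the list alone. Ptpn14 and Igfbp3, its most abundant members, had values of 0.02 ± 0.05 and 0.28 ± 0.13. Immediate early and AP-1 genes had 21 of 23 members positive, a median of 0.08 and an adjusted p of 0.0081, but the adjusted p = 0.893 with an estimated correlation. Fos and Egr1 had values of 0.18 ± 0.12 and 0.11 ± 0.08. Spinous and granular differentiation genes had 20 of 29 members positive and a median of 0.08 (adjusted p = 0.0138; adjusted p = 0.893 with an estimated correlation), and Krt10, a keratin of suprabasal cells, had a value of 0.08 ± 0.07 at 13940 CPM. Lipid and barrier synthesis had 18 of 24 members positive and a median of 0.05 (adjusted p = 0.0202; adjusted p = 0.893 with an estimated correlation), and glycolysis 15 of 15 and 0.07 (adjusted p = 0.0202; adjusted p = 0.893 with an estimated correlation). At single times these lists went both ways. Medians of glycolysis were -0.11 at ZT8, -0.01 at ZT12 and -0.10 at ZT16 but 0.42 at ZT20 (adjusted p = 1.3e-08; adjusted p = 0.64 with an estimated correlation; 0.109 with terms for sex-linked expression), where 4 libraries labelled WT and 1 labelled KO expressed Xist. Those of immediate early genes were 0.26 at ZT8 (adjusted p = 3.4e-05) and -0.28 at ZT12 (3.3e-05; 0.0030 with terms for sex-linked expression), and the adjusted p = 0.864 and 0.733 with an estimated correlation. Those of spinous and granular genes were -0.17 at ZT16 and 0.44 at ZT20 (adjusted p = 1.7e-06; adjusted p = 0.664 with an estimated correlation; 0.172 with terms for sex-linked expression). With terms for sex-linked expression, median edgeR fold changes of the immediate early, differentiation and glycolysis lists were below 0 (-0.02, -0.02 and -0.06). Their median differences in log2 CPM, the scale used by camera, were -0.016, -0.0055 and -0.059. Glycolysis then had an adjusted p of 0.0079 in camera, but the adjusted p = 0.857 with an estimated correlation. The adjusted p with these terms was 0.214 for YAP/TAZ targets and 0.837 for lipid and barrier synthesis, which had 0.0528 without members on chromosome 15.

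Cell cycle and melanocyte lists had negative medians in libraries labelled KO and were called by camera, with the same limit from the shuffles. G2 and M phase genes had 21 of 22 members negative and a median of -0.08 (adjusted p = 3.9e-05; adjusted p = 0.893 with an estimated correlation). The proliferation marker Mki67 had a value of -0.08 ± 0.05 and the topoisomerase gene Top2a -0.05 ± 0.05. S phase genes had 18 of 21 negative and a median of -0.04 (adjusted p = 0.0233; adjusted p = 0.893 with an estimated correlation), with Pcna, the replication clamp, at -0.04 ± 0.03. At single times these 2 lists also went the other way, with medians of 0.19 at ZT8 for G2 and M phase genes (adjusted p = 5.5e-08; adjusted p = 0.864 with an estimated correlation) and 0.16 at ZT20 for S phase genes (adjusted p = 1.7e-06; adjusted p = 0.64 with an estimated correlation). Melanocyte genes had 7 of 8 negative and a median of -0.20 (adjusted p = 0.0233; adjusted p = 0.853 with an estimated correlation; 0.117 without members on chromosome 15; 0.128 with terms for sex-linked expression), and Tyr, the tyrosinase gene of pigment synthesis, passed adjusted over the list alone (-0.94 ± 0.32) at 0.227 CPM. Of the 34 lists 10 were called with the preset correlation, 0 with an estimated correlation and 1 with fry.

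The remaining 24 lists, among them those of basal cells, inflammation and the clock, did not pass with all libraries. Leaving out 1 library let oxidative phosphorylation pass in 17 of 48 cases (adjusted p down to 0.0040, without KO ZT0 replicate 1), hair follicle in 16 (0.0127, without KO ZT0 replicate 2), sebaceous gland in 4 (0.0187, without KO ZT16 replicate 1), Langerhans and dendritic cell in 3 (0.0214) and stress and wound keratinocyte in 1 (0.0192), the last 2 values without WT ZT12 replicate 4. Basal keratinocyte genes (adjusted p = 0.202) included Krt5 at 10590 CPM and a value of 0.03 ± 0.05. The adjusted p was 0.314 for epidermal inflammation (26 measured, 1 called and 2 adjusted over the list alone, both lower), 0.389 for stress and wound keratinocyte, 0.873 for core clock, 0.0725 for nuclear-encoded oxidative phosphorylation, 0.873 for NRF2 and oxidative stress, 0.893 for senescence and p53, 0.87 for basement membrane and integrin adhesion, and 0.404 for heat shock. Among cell types it was 0.0609 for hair follicle stem and outer root sheath, 0.797 for anagen hair, 0.176 for sebaceous gland, 0.885 for fibroblast and dermis, 0.202 for Langerhans and dendritic cell, 0.873 for T cell, 0.609 for macrophage and monocyte, 0.993 for neutrophil, 0.344 for mast cell, 0.202 for endothelial, 0.708 for skeletal muscle, 0.727 for adipocyte, 0.873 for erythrocyte, 0.609 for Schwann cell and 0.609 for mitochondrially encoded genes. Adjusted over the list alone, 1 member passed in the hair follicle list (lower) and 1 in the mast cell list (higher). In edgeR, DESeq2 and limma-voom 0 genes were called among all genes in the 32 lists other than the interferon and inflammation lists, with 30 at an unadjusted p under 0.05. The median, mean and test differed in sign for the core clock, senescence, basement membrane, T cell, macrophage, neutrophil, erythrocyte and Schwann cell lists.

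At single times the calls were few and mostly repeated the averaged ones. The counts were 9 at ZT0, 9 at ZT4, 13 at ZT8, 4 at ZT12, 22 at ZT16 and 10 at ZT20, and 507, 1040, 628, 845, 1643 and 1415 genes had an unadjusted p under 0.05. Of these calls 9, 4, 13, 4, 16 and 10 were also called on average, and 6, 4, 10, 1, 14 and 7 were on chromosome 15. Col14a1 was called at each time. Snhg18 was lower at ZT0 (-1.34 ± 0.25), ZT8 (-1.16 ± 0.25), ZT16 (-1.15 ± 0.25) and ZT20 (-1.19 ± 0.25). Polr2k was lower at ZT0 (-0.91 ± 0.15), ZT4 (-0.78 ± 0.15), ZT8 (-0.83 ± 0.15) and ZT16 (-0.92 ± 0.15), and Rpl30 at ZT8 (-0.68 ± 0.14). Stk3 was higher at ZT0 (0.64 ± 0.12), ZT8 (0.68 ± 0.12), ZT16 (0.61 ± 0.12) and ZT20 (0.75 ± 0.12), Tspyl5 at ZT0 (2.28 ± 0.38), ZT8 (1.85 ± 0.38) and ZT20 (1.82 ± 0.38), and Mtss1 at ZT4 (0.46 ± 0.09). At ZT12 the calls were Col14a1, the pseudogene Gm5481 (7.57 ± 1.3, adjusted p = 0.0046), whose transcript matches that of Rpl30 at 95.7% over 345 bases, and 2 unnamed gene IDs, and Slc22a22, next by p, was not called, though it was with surrogate variables (adjusted p = 0.0277) and with make-up covariates (0.0386). The replicate block ended the calls of Snhg18 at ZT8, ZT16 and ZT20 (adjusted p = 0.0593, 0.0531 and 0.0636) and of Tspyl5 at ZT8 and ZT20 (0.0511 and 0.0622), and limma-voom those of Snhg18 at these 3 times (0.0812, 0.121 and 0.0897), Tspyl5 at ZT20 (0.0732), Lynx1 at ZT16 (0.0816) and Gm5481 at ZT12 (0.406). The call of Snhg18 at ZT20 also ended with terms for sex-linked expression (0.129), surrogate variables (0.165) and make-up covariates (0.145), and the last ended those of Snhg18 (0.0668) and Stk3 (0.1002) at ZT0. With only the 8 libraries of a time, the calls of Snhg18 (0.24), Polr2k (0.0575) and Stk3 (0.231) ended at ZT0, those of Polr2k (0.709) and Mtss1 (0.489) at ZT4, those of Snhg18 (0.3695), Rpl30 (0.0866) and Tspyl5 (0.604) at ZT8, those of the 2 unnamed gene IDs (0.153 and 0.257) at ZT12 and those of Snhg18 (0.299) and Stk3 (0.0833) at ZT20. Chance cannot be excluded for the count at ZT0, where 2 of 35 splits of the 8 libraries gave as many genes (9 real, 150 the highest other).

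Genes outside the averaged list appeared at ZT4 and ZT16. At ZT4, Gpr137b of lysosomal membranes was higher in libraries labelled KO (0.39 ± 0.08, adjusted p = 0.0226; 0.425 with only the 8 libraries of ZT4), as was BC023105 (2.92 ± 0.58), and Plac9a (-3.02 ± 0.63), Plac9b (-2.98 ± 0.59) and Gm9780 (-2.84 ± 0.58) were lower. At ZT16 the serine protease inhibitor genes Serpina3f (0.84 ± 0.16, adjusted p = 0.0092), Serpina3h (0.78 ± 0.15) and Serpina3i (0.74 ± 0.16) were higher, with the sterol hydroxylase gene Cyp27a1 (0.55 ± 0.12) and Tfcp2 (0.30 ± 0.07). Stmn1, which destabilises microtubules, was lower (-0.47 ± 0.09, adjusted p = 0.0095). On chromosome 15, Jrk (0.98 ± 0.19) was higher at ZT16, and Lynx1 (-0.88 ± 0.19) and Ptp4a3 (-0.74 ± 0.11) lower, and these 3 were also called on average. With only the 8 libraries of ZT16, 1 gene was called, and the calls of Serpina3f (adjusted p = 0.469), Jrk (0.414), Lynx1 (0.351), Polr2k (0.414) and Snhg18 (0.414) ended. Chance cannot be excluded for the count at ZT16, where 2 of 35 splits of these libraries gave as many genes (22 real, 58 the highest other). The Plac9 and Serpina3 genes belong to families of near-identical copies. Without the 3 libraries labelled WT that carry Gm5481, ZT4 gave 24 calls and ZT16 gave 11, and the calls of Mtss1 at ZT4 (adjusted p = 0.0731) and of Lynx1 (0.114) and Jrk (0.0518) at ZT16 ended. Counts rested on single libraries at 4 times. ZT4 gave 1 call without WT replicate 1 or without KO replicate 1, 2 without WT replicate 4 or KO replicate 2, 3 without WT replicate 2, 4 without KO replicate 4 and 5 without KO replicate 3. ZT8 gave 7 without WT replicate 1, 3 or 4, 8 without KO replicate 1, 6 without KO replicate 2 or 3 and 5 without KO replicate 4. ZT16 gave 12, 41 and 10 without WT replicates 2, 3 and 4 and 5 without KO replicate 2, and ZT20 gave 18 without KO replicate 2. Of the calls that the fixed rule named, Col14a1 held at every time without any 1 library, while at least 1 of the 8 libraries of its time ended that of Snhg18 (highest adjusted p 0.509, without WT ZT8 replicate 1), Polr2k (0.33) and Mtss1 (0.16) and Gpr137b (0.158; all without WT ZT4 replicate 1), Tspyl5 (0.23, without KO ZT20 replicate 3), Stk3 (0.137, without WT ZT0 replicate 3), Rpl30 (0.185, without WT ZT8 replicate 3), Gm5481 (0.0629, without WT ZT12 replicate 2), and Serpina3f (0.251), Lynx1 (0.251) and Jrk (0.146), without KO ZT16 replicate 2.

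Whether the genotype difference changed with time was tested for each gene. In edgeR 0 genes passed, with 1041 at an unadjusted p under 0.05, against 26 in DESeq2 and 0 in limma-voom. The 5 smallest p, none passing (adjusted p = 0.341), belonged to N4bp2, Plac9b, Gm9780, Gm5481 and Gpr137b, all of which passed in DESeq2 (adjusted p = 0.0042 for the first 3 and 0.0082 for the others). N4bp2 had a log2 fold change of -0.39 ± 0.09 at ZT12 and 0.23 ± 0.09 at ZT16, and Plac9b -2.98 ± 0.59 at ZT4 and 0.81 ± 0.47 at ZT8. Without WT ZT16 replicate 2 the count was 1.

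The clock ran in the epidermis of both labels. Arntl, which encodes BMAL1, fell from 73.4 CPM ± 5.37 (SD, n = 4) at ZT0 to 19.4 ± 2.5 at ZT12 in libraries labelled WT and from 72.4 ± 7.03 to 20.7 ± 1.9 in those labelled KO. Its fitted peak was at 23.7 ± 0.22 h and 23.6 ± 0.16 h (SE), with amplitudes of 0.972 ± 0.046 and 0.970 ± 0.038. Npas2, a partner of BMAL1, peaked near Arntl, at 23.9 and 0.219 h, and the repressor genes peaked later. Nr1d1, which encodes the repressor REV-ERB alpha, peaked at 8.34 and 8.41 h with 8.41- and 8.62-fold changes from trough to peak. The output gene Dbp peaked at 10.7 and 10.9 h (17.1- and 20.3-fold), Per2 at 14.0 and 13.7 h (24.1- and 28.7-fold), and Cry1 at 17.9 and 17.7 h (4.52- and 4.78-fold), in libraries labelled WT and KO in turn.

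**Figure D3:**
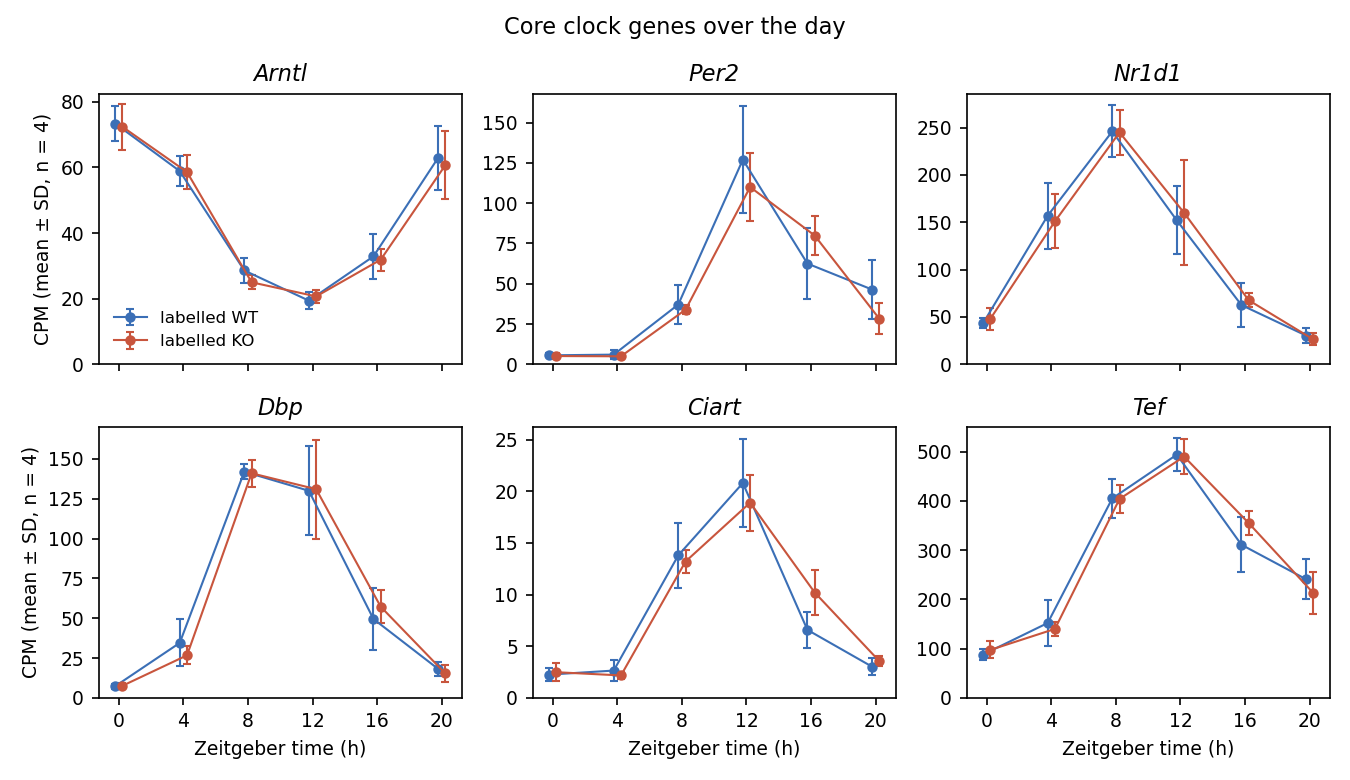
Levels of Arntl, Per2, Nr1d1, Dbp, Ciart and Tef in CPM against Zeitgeber time in hours, with mean and SD of 4 libraries per point and colours for the label. The lines of both labels run close together, with Arntl near 73.4 and 72.4 CPM at ZT0 and near 19.4 and 20.7 CPM at ZT12.

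Of 19 measured core clock genes 18 were rhythmic over both genotypes, and 19 adjusted over the list alone. The exception was Bhlhe40 (adjusted p = 0.122), which passed without WT ZT0 replicate 1 (adjusted p = 0.0135), with terms for sex-linked expression (0.043) and with surrogate variables (0.034). Amplitudes in libraries labelled WT and KO were 1.69 and 1.66 for Ciart, 1.44 and 1.5 for Per3, 1.11 and 1.16 for Tef, 0.970 and 1.03 for Nr1d2, 0.909 and 1.28 for Bhlhe41, 0.884 and 0.785 for Per1, and 0.708 and 0.850 for Nfil3. They were 0.552 and 0.529 for Cry2, 0.380 and 0.374 for Hlf, 0.177 and 0.203 for Clock, and 0.117 and 0.0975 for Rora. Among called genes with a mean of at least 1 CPM outside the core clock, the largest amplitude was that of Angptl7, a secreted angiopoietin-like protein gene (9.2- and 10-fold, peaks at 15 and 14.9 h). Glucocorticoid-induced Fkbp5 (3.99- and 5.36-fold) and Tsc22d3 (3.63- and 3.99-fold) peaked near 15.1 and 14.3 h in libraries labelled WT, and Mthfd1l, a mitochondrial folate enzyme gene, changed 4.64- and 4.47-fold. Spock2 (4.05- and 3.17-fold) and Tspear (3.52- and 3.1-fold) were also among the largest. Stfa1 (adjusted p = 0.0175) and Cstdc5 (0.0334) were called in libraries labelled WT but not KO (0.236 and 0.342). These calls ended without WT ZT12 replicate 4 (adjusted p = 0.935 and 0.907), in limma-voom (0.517 and 0.781), with the replicate block (0.0932 and 0.129) and with surrogate variables (0.0987 and 0.162), that of Cstdc5 also without the 3 libraries labelled WT that carry Gm5481 (0.0786), and the difference in rhythm did not pass (adjusted p = 0.9998 for both). Actr3b, E230001N04Rik, Ifi203-ps and 1 unnamed gene ID were among the largest in libraries labelled KO. The calls of Actr3b and Ifi203-ps ended without KO ZT4 replicate 3 (adjusted p = 0.061) and without KO ZT12 replicate 1 (adjusted p = 0.0644), the latter also with make-up covariates (0.0915).

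Genes of cell division cycled as a body. All 21 measured S phase genes were rhythmic over both genotypes, with a mean peak at 13.6 h and a median change of 1.82-fold, and Mcm2, a subunit of the replicative helicase, changed 2.56-fold. All 22 G2 and M phase genes were rhythmic with a mean peak at 0.732 h and a median change of 1.87-fold. Ccnb1, the cyclin B1 gene of mitotic entry, was at 27.4 CPM ± 3.86 (SD, n = 4) at ZT0 and 12.5 ± 2.30 at ZT12 in libraries labelled WT, and at 26.1 ± 2.0 and 10.5 ± 0.856 in those labelled KO. Against all tested genes the adjusted p was 1.3e-11 for the S phase list, 7.0e-12 for the G2 and M phase list and 6.8e-09 for the core clock (Fisher's exact test over 34 lists). Lists with fewer genes rhythmic over both genotypes than the rest were immediate early and AP-1 (0 of 23, adjusted p = 0.0117), anagen hair (0 of 21, 0.0151), T cell (0 of 19, 0.021) and fibroblast and dermis (0 of 16, 0.0478). Adjusted over the list alone the edgeR count was also 0 in these 4 lists, with 1 gene, of the T cell list, at an unadjusted p under 0.05, and DESeq2 called 1 in that list and limma-voom 0 in each. In the test over both genotypes opposite phases cancel, and in libraries labelled WT alone 1 fibroblast and dermis gene was rhythmic, and 5 adjusted over the list alone.

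**Figure D4:**
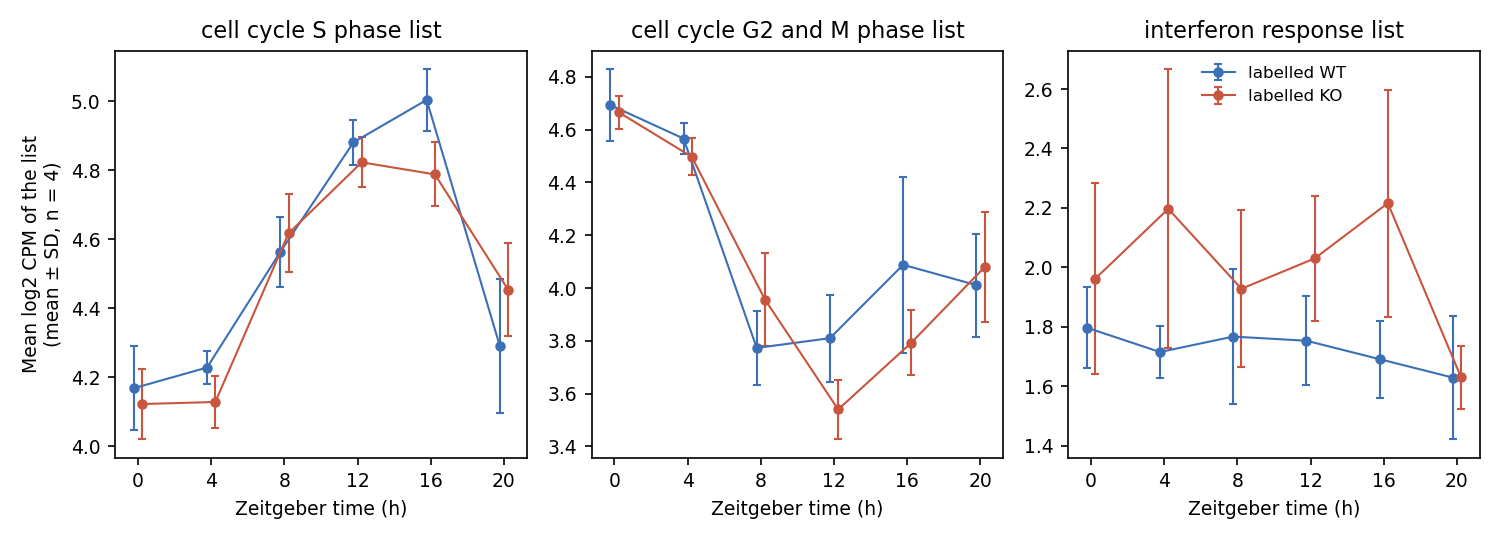
Mean log2 CPM of the S phase, G2 and M phase and interferon response lists against Zeitgeber time in hours, with mean and SD of 4 libraries per point and colours for the label. S phase peaks near 13.6 h and G2 and M phase near 0.732 h. The mean of the interferon list is higher in libraries labelled KO, by 0.525 at ZT16, but level at ZT20. There it differs by 0.00107, and the median difference is -0.0279.

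Rhythmic genes, the clock among them, made up similar shares under both labels in the cosine fit, but not in the 5-df test, which assumes no shape. In libraries labelled WT 1972 genes (11.6%) passed, and in those labelled KO 2075 (12.2%). Both lists shared 1208 genes, 61.3% of the first, where independent lists would share 239.7. Over both genotypes 4533 genes (26.6%) were rhythmic, with 6321 at an unadjusted p under 0.05. The most common peak was near ZT16, with 514 (26.1%) of those called in libraries labelled WT and 530 (25.5%) in those labelled KO. Near ZT0, ZT4, ZT8, ZT12 and ZT20 there were 289, 320, 260, 363 and 226 in the former and 368, 266, 255, 390 and 266 in the latter. The 5-df test called 4881 genes (28.6%) in libraries labelled WT and 2695 (15.8%) in those labelled KO, and with terms for sex-linked expression 6298 (36.9%) and 3214 (18.8%).

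In the cosine fit, clock genes did not differ detectably in rhythm between the labels, nor did any other gene when adjusted over all genes tested. Adjusted over the list alone, 5 fibroblast and dermis genes, Col1a1 among them, and 2 macrophage and monocyte genes did, and with terms for sex-linked expression 0 and 2 genes of these lists passed. For the dermal genes a different rhythm cannot be told apart from uneven dermal content of the libraries. In edgeR 0 genes had a different rhythm, with 395 at an unadjusted p under 0.05, against 0 in DESeq2 and 0 in limma-voom, and 0 core clock genes passed adjusted over the list alone (0 at an unadjusted p under 0.05). For Arntl the peak differed by -0.10 ± 0.27 h and for Per2 by -0.25 ± 0.29 h. Ciart peaked 0.732 ± 0.25 h later in libraries labelled KO (unadjusted p = 0.241), and Hlf differed by -1.41 ± 0.49 h (unadjusted p = 0.216). The 5 smallest p, none passing (adjusted p = 0.9998), belonged to Ccdc148, Stfa1, Itgb3, Dand5 and Zfp473. Over the 4533 genes called by the test over both genotypes, which favours genes with like phases under both labels, the median log2 ratio of amplitudes, KO over WT by label, was 0.0072 ± 0.0671 (SE), a 95% interval of 91.7% to 110%, and the median amplitude was 0.142 and 0.143 in libraries labelled WT and KO. Without WT ZT16 replicate 2 the count of genes with a different rhythm was 1.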

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

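The tests of dermal cells, of transcription across the targeted allele, of other-strain DNA, of sex-linked imbalance for chromosome 15 and of T cells or macrophages were chosen after the results they concern had been seen.

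Single libraries stood apart from the other 3 of their group in 6 of 144 groups by Dixon's test, where chance gives about 1 in 20 groups. For Col14a1 they were WT ZT4 replicate 3 at 2.47 CPM (others 0.397 to 0.719), KO ZT12 replicate 2 at 61.1 CPM (others 52.6 to 53.8) and KO ZT16 replicate 2 at 72.3 CPM (others 56.7 to 58.1). The mean log2 CPM of the YAP/TAZ target list was 5.59 in KO ZT0 replicate 1 (others 5.51 to 5.52). That of the MHC class I presentation list was 7.72 in WT ZT12 replicate 3 (others 7.58 to 7.60). Glycolysis genes averaged 7.66 in WT ZT0 replicate 1 (others 7.0 to 7.11).

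Differences between the labels over the day passed for some list members when adjusted over the list alone, though none passed over all genes. In the fibroblast and dermis list 5 members had a different rhythm, the collagen genes Col1a1, Col1a2 and Col3a1 and the matrix gene Lum (adjusted p = 0.0302 each) and Pdgfra (0.0391). The first 4 peaked at 13.2 to 14.7 h in libraries labelled WT and at 23.5 to 24 h in those labelled KO, and 0 of the 5 passed with terms for sex-linked expression. Dermal content varied between libraries (Col1a1 from 0.288 to 95.1 CPM in those labelled WT and 0.441 to 46.4 CPM in those labelled KO). These genes may follow it together, so a shift of rhythm cannot be told apart from uneven dermal content. In the macrophage and monocyte list 2 members had a different rhythm, the complement gene C1qc (0.0216) and the mannose receptor gene Mrc1 (0.0118), and 2 passed with those terms. For the genotype by time interaction 1 member passed in each of the YAP/TAZ target list (Ptpn14, 0.0279), the basal keratinocyte list (Dst, 0.0322) and the heat shock list (Hspa4l, 0.0368), and 1 in each passed with those terms.

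Col14a1, the gene labelled as knocked out, averaged 61.3 CPM in libraries labelled KO and 1.23 CPM in those labelled WT. The tables argue against more dermal cells in the libraries labelled KO, since the fibroblast and dermis list differed by 0.173 (95% interval -0.26 to 0.606), far from the 5.69 of Col14a1. Labels of the genotypes exchanged throughout stay open. The rho of 0.543 between Col14a1 and that list has the sign that an intact gene read from dermal cells would give. It pools the 6 times, and Col14a1 itself differed by time (71.4 CPM at ZT4 and 53.5 CPM at ZT8 in libraries labelled KO), so it does not decide the question. The SD of Col14a1 in these libraries, 0.195, lies far below the 0.726 of the list, which argues against a level set by dermal content alone. Transcription across the targeted allele, such as from a promoter in a targeting cassette, may give the same counts and such an even level (SD 0.195), and counts per gene do not show where in the gene the reads lie, so these explanations cannot be told apart here. A biological rise of Col14a1 was not tested.

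Called genes lay on chromosome 15 in 37 of 51 placed cases, in both directions and on both sides of Col14a1. An imbalance of sex-linked expression is argued against, since 100% of these 37 calls stayed with terms for it. A candidate explanation that stays open is DNA of another strain that travelled with the targeted allele, which would place calls around Col14a1, and 72.5% were on its chromosome. An effect of the targeted gene itself on these genes was not tested and stays open too. Outside the chromosome, 4 of the 13 called genes with a transcript sequence (30.8%) matched a called chromosome 15 gene, Gm5481, Gm9703 and Gm6109 matching Rpl30 at 95.7%, 97.7% and 96.5% and Mzt1 matching Erich5 at 91.5% over 152 bases, so for these 4 shared reads and a change of the gene itself cannot be told apart from counts per gene. The same limit holds for Rpl30 and Erich5.

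Interferon response genes were higher in libraries labelled KO, by 0.268 ± 0.0724 log2 in the list mean. Sex-linked imbalance as the whole cause is argued against by a difference of 0.294 within time and sex-linked type (0.229 among libraries with Xist and 0.363 among the others), and 1 library with a high response by 90.6% of the difference staying without KO ZT4 replicate 1, the lowest share. More T cells or macrophages in the libraries labelled KO may contribute and stay open: with terms for sex-linked expression the T cell list had a median of 0.138 against 0.21 for the interferon list, but without them it was -0.0023 and that of macrophages -0.12. The most abundant markers, Trbc2 at 36.1 CPM and Csf1r at 17.0 CPM, had values of 0.05 ± 0.05 and -0.13 ± 0.15, and of -0.02 and 0.04 with terms for sex-linked expression. A biological effect of the genotype, or of strain DNA linked to it, was not tested and stays open.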

How the results depend on the processing

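Alternatives based on only the libraries with Xist or only those with Y-linked expression, on sex-linked terms in the 5-df and list tests, on chromosome 15, and on leaving out the 3 libraries labelled WT that carry Gm5481 were chosen after seeing the data. The averaged count of 58 was 58 with the replicate block and with RLE, and 57 without a filter, with make-up covariates and without those 3 libraries. It was 44 with the stricter filter, 81 in DESeq2, 54 in limma-voom and 76 with surrogate variables. It was 185 with terms for sex-linked expression, for which the cause was not tested. Adjusted over the genes not placed on chromosome 15 alone, which hold 21 of the 58, 7 of them unplaced, it was 14. By construction it was smaller at 24 with glmTreat and, with fewer samples, at 26 in libraries with Xist and 34 in the others. DESeq2 gave 24 at ZT4, 36 at ZT16, 17 at ZT20 and 26 for the interaction, limma-voom 5 at ZT20, and sex-linked terms 126 at ZT4 and 131 at ZT16, and the cause was not tested. The 8 libraries of a time alone, fewer samples, gave 5 at ZT0, 2 at ZT12 and 1 at ZT16. The stricter filter, with fewer genes, gave 4 at ZT4, and no filter, with more genes, gave 1 of different rhythm. Without the 3 libraries labelled WT that carry Gm5481 there were 24 at ZT4 and 11 at ZT16, and the cause was not tested. The 5-df test called 4881 genes with any difference among the times in libraries labelled WT, and with sex-linked terms 6298 in these and 3214 in those labelled KO. Lists called fell from 10 to 0 with an estimated correlation, with or without sex-linked terms, and to 1 with fry. For these and for the 5-df test the cause was not tested. With sex-linked terms 3 lists reversed, each with both correlations: immediate early at a median log2 CPM difference of -0.0157 (adjusted p = 0.837; 0.984 with an estimated correlation), spinous and granular at -0.00553 (0.762; 0.984) and glycolysis at -0.0594 (0.00787; 0.857), and the cause was not tested. The other alternatives kept these counts within 1.5 times, and no gene called and named in the averaged effect reversed under any alternative. Named genes that did not pass did, such as Fos (0.18 to -0.01), Krt5 (0.03 to -0.02), Trbc2 (0.05 to -0.02) and Csf1r (-0.13 to 0.04) with sex-linked terms. Of the calls named at single times, 18 ended with the 8 libraries of that time alone, 6 in limma-voom, 5 with the block, 3 with make-up covariates, 3 without the 3 libraries that carry Gm5481 and 1 each with surrogate variables and sex-linked terms. Col14a1 differed by 5.67 with library totals alone. Without 1 library, counts ran from 48 to 68 averaged, 6 to 11 at ZT0, 1 to 9 at ZT4, 5 to 9 at ZT8, 3 to 5 at ZT12, 5 (without KO ZT16 replicate 2) to 41 (without WT ZT16 replicate 3) at ZT16, 7 to 18 at ZT20, 0 to 1 for the interaction and for different rhythm, 1701 to 2268 and 1752 to 2351 for rhythm in libraries labelled WT and KO, 4258 to 4937 over both, and 5 (without WT ZT4 replicate 1) to 13 lists (6 without KO ZT16 replicate 3). The amplitude ratio ran from -0.06 to 0.05 log2. The interferon, MHC class I and G2 and M lists stayed called without any 1 library, and the others of the 10 did not: YAP/TAZ was lost in 1 case (adjusted p = 0.0569, without WT ZT4 replicate 1), immediate early in 5 (up to 0.095), melanocyte in 7 (0.0887), lipid in 8 (0.131), spinous in 9 (0.208), glycolysis in 16 (0.135) and S phase in 18 (0.164). Lists gained without 1 library were oxidative phosphorylation (17 cases), hair follicle (16), sebaceous gland (4), Langerhans (3) and stress keratinocyte (1). At the real depth and number of replicates, but with genes drawn independently, simulated changes of 1.5-fold at 1 time were recovered in 70% of cases and averaged ones in 96%.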

Other observations

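Of the tests in this part, the list tests with terms for sex-linked expression, the values of Gm5481 and the count without 3 libraries were chosen after the results had been seen. The lists also passed at single times in camera with the preset correlation, in libraries labelled KO against those labelled WT. For the averaged effect that test called as many lists in 48 of 100 shuffles of genotype, so such calls are weak evidence. Interferon response genes were higher at ZT4 (median difference in log2 CPM 0.40, adjusted p = 6.4e-12), ZT12 (0.24, 2.6e-04) and ZT16 (0.40, 2.7e-10), with values of 0.11 at ZT0 and ZT8 and -0.03 at ZT20 (where the mean was 0.00107), and the adjusted p = 0.197, 0.733 and 0.357 with an estimated correlation. G2 and M phase genes were higher at ZT8 (0.19, adjusted p = 5.5e-08) and lower at ZT12 (-0.26, 8.9e-15) and ZT16 (-0.32, 2.7e-13), and the adjusted p = 0.864, 0.5 and 0.366 with an estimated correlation. S phase genes were lower at ZT4 (-0.10, 0.0013) and ZT16 (-0.22, 1.9e-11) and higher at ZT20 (0.16, 1.7e-06), and the adjusted p = 0.804, 0.357 and 0.64 with an estimated correlation. Sebaceous gland genes, of lipid-secreting cells, were lower at ZT0 (-0.70, 2.3e-04) and ZT20 (-1.15, 3.1e-06) and higher at ZT12 (0.48, 0.0043). For these the adjusted p = 0.864, 0.64 and 0.733 with an estimated correlation, and 0.78, 0.109 and 0.18 with terms for sex-linked expression, and WT ZT20 held 4 libraries with Xist and KO ZT20 held 1. With terms for sex-linked expression, interferon response genes also passed at ZT0 (adjusted p = 0.0011) and sebaceous gland genes at ZT4 (0.0389) and ZT8 (2.5e-04), all higher, and G2 and M phase genes at ZT0 (0.0015) and ZT4 (0.0213) and S phase genes at ZT12 (0.0242), all lower. These tests were not repeated with an estimated correlation. Without those terms no list at any time passed with an estimated correlation (smallest adjusted p = 0.197).

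Other groups kept time of day as well, over both genotypes. Among lipid and barrier synthesis genes 12 of 24 were rhythmic (13 adjusted over the list alone) with a mean peak at 1.56 h, and among heat shock genes, which encode chaperones, 6 of 14 were (9 adjusted over the list alone) with a mean peak at 19.9 h. YAP/TAZ targets had 10 of 21 (11 adjusted over the list alone), and glycolysis genes 6 of 15 with a mean peak at 19.2 h. Against all tested genes these shares did not pass (Fisher's exact test, adjusted p = 0.0754 for lipid and barrier synthesis, 0.502 for heat shock, 0.126 for YAP/TAZ targets and 0.525 for glycolysis). Terms for sex-linked expression called 2 lists lower in libraries labelled KO that did not pass without them, nuclear-encoded oxidative phosphorylation (adjusted p = 6.1e-13) and heat shock (0.0079), and the T cell list higher (0.030), but the adjusted p = 0.288, 0.857 and 0.857 with an estimated correlation.

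The pseudogene Gm5481 was at 9.78 to 28.4 CPM in all 24 libraries labelled KO and at 0 to 0.216 CPM in 21 of those labelled WT. The other 3 labelled WT, ZT4 replicate 3, ZT4 replicate 4 and ZT16 replicate 2, were at 9.64, 14.1 and 13.3 CPM. Whether these 3 animals came from another cross or were heterozygous near Rpl30 was not tested, and it bears on what their label and the chromosome 15 fold changes mean. Without them 57 genes were called on average. In the same 3 libraries Tspyl5 was at 1.69, 0.839 and 1.09 CPM (0.0766 to 0.601 in the 21 and 0.651 to 2.66 in those labelled KO). Stk3 was at 13.6, 16.4 and 11.9 CPM (9.71 to 14.9 and 12.7 to 22.2), Polr2k at 7.67, 6.71 and 10.8 CPM (7.46 to 13.2 and 4.3 to 7.46), Rpl30 at 307, 356 and 346 CPM (296 to 497 and 199 to 394), and Mtss1 at 43.4, 37.3 and 40.2 CPM (34.2 to 52.2 and 44.6 to 61.9).

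Other splits of the samples were counted against the real ones, the real split included. For the averaged effect 2 of 100 shuffles of genotype within time gave as many genes (58 real, 295 the highest other). For genes not placed on chromosome 15 it was also 2 of 100 (21 real, 284), and with sex-linked terms 1 of 100 (185 real, 52). These shares argue against chance for each count. Of the 21 genes, 14 were placed elsewhere and 7 had no known position. Of the 14, 4 had a transcript match to a called chromosome 15 gene. The 21 are therefore not all known to lie away from that chromosome. The shuffle with 295 genes, which points to a structure of the samples, put 6 libraries with Xist on one side and 18 on the other, and the next highest gave 4. Only the real split, 1 of 35, gave as many genes at ZT4, ZT8, ZT12 and ZT20. The real and highest other counts there were 9 and 4, 13 and 1, 4 and 1, and 10 and 2 in turn. That is the smallest share this test can give, and it was not adjusted over the 6 times, so it does not exclude chance. Each other split also changed the labels at the other times, which can widen the shared spread, so the comparison may favour the real split. Chance cannot be excluded either at ZT0 (2 of 35, with 9 real and 150 the highest other) or ZT16 (2 of 35, with 22 real and 58). The ZT0 split with 150 genes parted libraries with Xist 1 against 3, and the ZT16 split with 58 parted them 3 against 0, but a ZT4 split that also parted them 3 against 0 gave 4 genes. For the interaction (0 real, 447) and the different rhythm (0 real, 7) 100 of 100 splits by shuffling gave as many, as any would against a count of 0, so these say nothing of chance. The shuffle with 447 genes also points to a structure of the samples, and it put 10 libraries with Xist on one side and 14 on the other, so the structure was not traced to sex-linked type. For rhythm, shuffles of time within genotype gave as many genes in 1 of 100 in libraries labelled WT (1972 real, 189), 1 of 100 in those labelled KO (2075 real, 2) and 1 of 100 over both (4533 real, 2002). That is the smallest share this test can give, and it argues against chance for these counts. The shuffle with 2002 genes points to a structure of the samples here too. Chance cannot be excluded for the amplitude ratio (97 of 100, with 0.0072 real and 0.201) or the number of lists called (48 of 100, with 10 real and 16). For the interferon list mean only the real split, 1 of 100, gave as large a value (0.268 real, 0.212 the highest other in size). That list was singled out after the results were seen, as the one with the clearest rise. The share was not adjusted over the lists, so it does not exclude chance for it.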
